A study of Ovis aries with 12 samples.

How the data were processed

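RNA from the biceps femoris, a hind-limb muscle, of sheep fetuses near term was hybridised to a 1-colour Agilent array. There were 12 arrays, 6 from fetuses of ewes infused with cortisol and 6 from fetuses of control ewes, with 1 array per fetus. Per the labels, cortisol was given at 1 mg/kg/day from day 115 of pregnancy until necropsy at day 139 to 144, soon after labour began, and 7 ewes per arm were treated. The series holds 6 arrays per arm, and samples of the remaining ewes were not analysed here. The labels name the biceps femoris as the tissue in their title and sample fields, whereas their treatment text speaks of the left ventricular free wall of the heart and gives for it fewer samples per group than the series holds.

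Per the labels, RNA was extracted with Trizol and RNeasy columns, and 500 ng was labelled with Cy3. Scans were read by the authors with Agilent Feature Extraction 10.1.1.1. Per the file headers, the scanner files hold spot intensity as mean and median pixel brightness, the local background, and a processed intensity that was background-subtracted and detrended but not scaled between arrays. Per the file headers, the remaining columns used are other values, 0 or 1 flags for each spot, such as well above background or outlier. The deposited table of the series holds log2 values. Their distributions are nearly equal, as by quantile normalization, since the quartiles of the 12 columns differ by at most 0.034. Their order within each array is that of the median signal minus its background, with a Spearman correlation of 1 on all 12 arrays. The tool used for that normalization is not given in the sources used here.

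The array holds 15744 spots, of which 15208 are not controls and make up 15008 probes. Spots of the same probe were averaged, and outlier-flagged spots were left out. The processed intensity was put on the log2 scale and each array's 75th percentile over non-control probes was subtracted, so all signals are log2 units relative to that percentile. A probe was tested where it was well above background on at least 6 of 12 arrays, which left 10734 probes and removed 4274. Between 66.4% and 76.0% of probes were well above background on an array. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.21.

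Gene names came from the array's own annotation and the reference's table of sheep genes. A RefSeq accession named 713 probes, an Entrez number 134, a symbol 497 and a synonym 20. A further 84 were named from the array's name or description by a table made by hand after the array's names, but not the comparison, had been read, and 227 kept the array's own name. No gene name could be given to 13319 probes, and 14 matched several genes. The named part is therefore 1675 probes with 1029 names. For each gene the probe with the highest mean signal over all 12 arrays was used, which gave 716 measured genes.

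Cortisol and control arrays were compared probe by probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Intervals are at 95%. There were 34 gene lists fixed before the data were examined, and 24 with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01 against the named genes. Camera with an estimated correlation and limma's fry were run beside it. fry asks whether the genes of a list move on balance in 1 direction. Array quality was compared by exact permutation tests, two-sided. Reading and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

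The genes named were chosen by a rule fixed before the data were examined. Had genes passed the adjusted threshold, up to 15 per direction with the largest change would have been named. As none did, the 10 higher and 10 lower genes with the smallest unadjusted p were named as values that did not pass. The rule adds up to 4 members of a list past the threshold, up to 2 members of every other list, and a set of glucocorticoid-related and muscle genes. It named 82 genes. FKBP5, TSC22D3, KLF15, PDK4 and TRIM63 belong to that set but are not on the array by name, and PER1 was not measured above background.

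Alternatives fixed beforehand were normexp background correction with an offset of 50, quantile and median scaling, the deposited log2 values, other filters, outlier spots kept in, slide, slide row and replicate number as blocks, each slide alone, a different variance model, array weights, other thresholds, 1 probe per gene, and each array left out in turn. Further alternatives were chosen after seeing the data: leaving out the array of each group that correlates least with its own group, leaving out the control arrays with the highest AHSG signal, lists matched without the hand-made names, camera against all tested probes, and an exact permutation test of each list's mean. The tests were checked on simulated data with 10734 probes. At a 1.5-fold change 10.4% of changed probes were called, at 2-fold 50.7% and at 4-fold 93.9%, and 2 of 10534 unchanged probes were called. A simulated shift of -0.50 in the oxidative phosphorylation list was recovered as -0.50, with 0 of the other lists called. Without a shift the simulation called 0 lists, whereas 71 of 100 splits of the real arrays, the real one included, gave at least 1. The simulation therefore says little on false list calls in the real data.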

Results

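Expression was measured in biceps femoris of 12 late-gestation sheep fetuses, 6 from ewes infused with cortisol over the last weeks of pregnancy and 6 from control ewes. The skeletal-muscle regulators MYOD1 and MYOG were well above background on all 12 arrays, at log2 signals of -0.35 to 2.59 for MYOD1 and -0.48 to 1.02 for MYOG. The 75th percentile of signal lay between 187 and 448 intensity units per array, and between 9958 and 11403 probes per array were well above background. All signals below are log2 units relative to that percentile, with n = 6 arrays per group. The comparison asks how raised maternal cortisol before birth alters the muscle transcriptome of the fetus.

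The measured genes of the mitochondrial respiratory chain and ATP synthase, 8 of the 79 listed, had lower mean signals in the cortisol group, a shift whose call depends on the set test. All 8 nuclear-encoded oxidative phosphorylation genes were lower, among them COX5A of complex IV, NDUFA2 and NDUFA12 of complex I, SDHD of complex II, and the ATP synthase subunits ATP5MC1, ATP5MC2, ATP5PD and ATP5PO. NDUFA2 averaged 6.50 ± 0.073 (SD) in controls and 6.01 ± 0.36 after cortisol, and all 6 cortisol arrays lay below every control. ATP5MC1 averaged 8.99 ± 0.12 and 8.63 ± 0.18, with 5 cortisol arrays below every control. COX5A averaged -1.83 ± 0.27 and -2.57 ± 0.53, a log2 fold change of -0.74 (95% interval -1.24 to -0.24), and ATP5PO averaged 7.14 ± 0.15 and 6.82 ± 0.16.

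This was the 1 list of 24 past the threshold in camera, with a mean log2 fold change of -0.39 and an adjusted p of 4.94e-06, but adjusted p = 0.513 with an estimated correlation. fry gave an adjusted p of 0.0731. Per array, the mean of the 8 genes was 4.49 ± 0.10 in controls and 4.10 ± 0.22 after cortisol, an exact permutation p of 0.00433 that became 0.104 when adjusted over the 24 lists. With this number of arrays, 1 list alone could not pass that adjustment whatever its values. The mean of the 8 genes was 3.86, 4.20, 3.95, 4.28, 3.92 and 4.40 on cortisol arrays 1 to 6 and between 4.32 and 4.62 on control arrays. Of the 8 members, 5 passed when adjusted over the list alone and 0 passed over all probes. Here and below, an adjustment over the list alone takes no account of the other lists. Within the 3 sets of arrays that share a slide and row, each with 2 control and 2 cortisol arrays, the mean difference was -0.46, -0.30 and -0.42. In 71 of 100 splits of the 12 arrays, the real one included, camera placed at least 1 list past the same threshold.

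**Figure D1:**
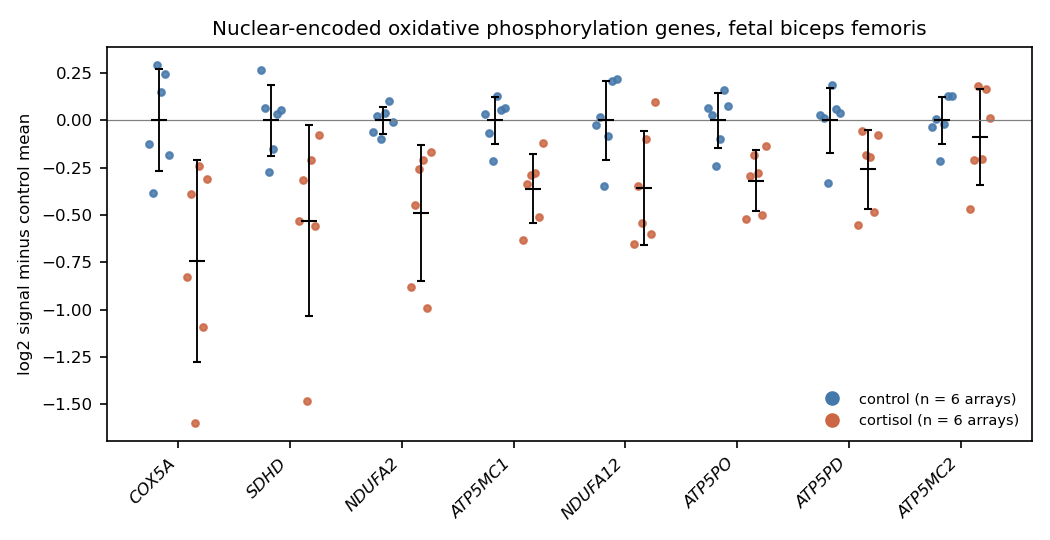
Log2 signal minus the control mean for the 8 measured nuclear-encoded oxidative phosphorylation genes, with 1 point per array and black bars for the mean and SD (n = 6 arrays per group). The cortisol mean lies below the control mean for all 8 genes, from -0.74 for COX5A to -0.09 for ATP5MC2.

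No single gene passed the test. Among the measured genes, those nearest to the threshold in the higher direction were FCER1G and ITGB2, which are leukocyte genes, the lipid-droplet gene PLIN2, the apoptosis gene BAX, MYC, GRINA, PABPC1, HOXA4, SLAN and FLAP. In the lower direction they were COX15, which serves cytochrome oxidase assembly, the oxygen-binding muscle gene MB, the water channel AQP4, ENDOG, ATP6V1E1, COX5A, YEATS4, ITGB6, HAND1 and MYF5. PLIN2 averaged -0.69 ± 0.51 in controls and 0.35 ± 0.67 after cortisol, a log2 fold change of 1.04 (95% interval 0.37 to 1.71). MB averaged 6.35 ± 0.37 and 4.88 ± 1.29, a log2 fold change of -1.46 (95% interval -2.50 to -0.43), with all 6 cortisol arrays below every control. AQP4 averaged 4.45 ± 0.33 and 3.25 ± 0.94. A second probe for HAND1 had the other sign, at 0.08 against -0.47.

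In limma, 0 of 10734 probes passed an adjusted p of 0.05, and the smallest adjusted p was 0.690. The smallest unadjusted p, 0.00012, belonged to a lower probe without a gene name. Among measured genes the smallest was 0.0043, for FCER1G. At an unadjusted p under 0.05 there were 740 probes, 230 higher and 510 lower, where 536.7 are expected by chance. Of the 716 measured genes, 54 had an unadjusted p under 0.05, 26 higher and 28 lower, and 0 passed when adjusted over the genes alone.

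Direct glucocorticoid targets were thinly covered, since 3 of the 32 listed genes were measured. CEBPB, TXNIP and NFKBIA all had higher means after cortisol, with log2 fold changes of 0.89, 0.71 and 0.17. With slide 1 alone, CEBPB and TXNIP were both at 0.08. CEBPB averaged -1.95 ± 0.67 in controls and -1.06 ± 0.86 after cortisol. The glucocorticoid receptor gene NR3C1 averaged 1.36 ± 0.16 and 1.46 ± 0.28, and the mineralocorticoid receptor gene NR3C2 1.09 ± 0.52 and 1.00 ± 0.53. HSD11B1, whose enzyme regenerates active cortisol, averaged 0.22 ± 0.36 and 0.68 ± 0.66, a log2 fold change of 0.47 that was 0.20 without cortisol array 3. HSD11B2, whose enzyme inactivates it, averaged -3.77 ± 0.33 and -3.96 ± 0.67. Corticosteroid receptor and metabolism genes were 2 higher and 3 lower of 5 (camera adjusted p of 0.864).

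Protein breakdown was represented by 10 muscle atrophy and autophagy genes, 7 higher and 3 lower. The ubiquitin ligase gene FBXO32 averaged -0.45 ± 0.84 in controls and 1.08 ± 1.81 after cortisol, with 3 of the 6 cortisol arrays above every control. CTSB averaged 0.50 ± 0.28 and 0.76 ± 0.29. Of 4 proteasome genes 3 were higher and 1 lower, with log2 fold changes of 0.18 for PSMD4 and -0.11 for PSMB7. The glucose transporter gene SLC2A4 had a log2 fold change of -0.76 (95% interval -1.36 to -0.15), IGFBP5 of -0.64, IGF1 of 0.19 and IGF2 of 0.16. The muscle growth inhibitor MSTN had 0.81, which became 0.11 without control array 3. The 14 insulin and IGF signalling genes were 7 higher and 7 lower. Camera gave adjusted p of 0.394 for atrophy, 0.864 for the proteasome and 0.865 for insulin and IGF signalling.

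All 5 measured fast-fibre genes had higher means after cortisol, with a mean log2 fold change of 0.72, but this rests on control array 3. Without it 2 were higher and 3 lower, with a mean of 0.088. MYH1 averaged 4.65 ± 2.06 in controls and 5.82 ± 0.48 after cortisol, and on control array 3 it was 0.50 against 4.92 to 5.93 on the other controls. The slow-fibre list had 1 measured gene, MYH7, which averaged 1.62 ± 1.31 and 0.62 ± 0.99, and without control array 3 its log2 fold change was -0.53. MYH2 and MYOD1 had log2 fold changes of 1.06 and -0.52, which were 0.29 without control array 3 and -0.17 without cortisol array 1. The lower MYOD1 mean did not come from 1 array, as 3 cortisol arrays lay below every control. On cortisol arrays 1 to 6 MYOD1 was -0.35, 2.59, 1.01, 2.14, 0.49 and 2.52, against 1.63 to 2.27 on control arrays. MYF5 averaged -4.09 ± 0.36 and -4.69 ± 0.32. Of the 4 developmental and myogenic genes (1 higher, 3 lower), it was the 1 to pass when adjusted over the list alone. It did not pass over all probes and was well above background on only 3 of the 6 cortisol arrays. Camera gave adjusted p of 0.203 for fast-fibre and 0.392 for developmental and myogenic genes.

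Fuel-use genes outside the respiratory chain had means that differed in both directions. Of 7 fatty acid uptake and oxidation genes, 4 were higher and 3 lower. PLIN2 passed when adjusted over the list alone but not over all probes. LPL averaged 2.29 ± 1.13 in controls and 1.21 ± 0.45 after cortisol, with all 6 cortisol arrays below every control, and its log2 fold change of -1.08 was -0.63 without control array 3. Of 11 glycolysis and glycogen genes 3 were higher and 8 lower, including SLC16A1 at -0.39 and PFKL at -0.32, or -0.10 without control array 3. Of 5 mitochondrial biogenesis genes 1 was higher and 4 lower, with VDAC1 at -0.38, NRF1 at 0.31 and PPARGC1A at -0.09, whose probes differ in sign. Of 5 amino acid metabolism genes 2 were higher and 3 lower, with GLUD1 at -0.41 and SHMT1 at -0.40, the latter from a probe that the array itself names SHMT2. The 1 measured pyruvate dehydrogenase and TCA cycle gene, ME1, had a log2 fold change of 0.31. Camera gave adjusted p of 0.865, 0.786, 0.786 and 0.392 for the 4 lists of fatty acid, glycolysis, mitochondrial biogenesis and amino acid genes. No mitochondrially encoded respiratory gene was measured.

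Leukocyte genes were 3 higher and 1 lower of 4, and FCER1G and ITGB2 passed when adjusted over the list alone. Over all probes, their adjusted p in limma was 0.690 and 0.692. FCER1G averaged -1.96 ± 0.25 in controls and -1.37 ± 0.30 after cortisol, with 4 cortisol arrays above every control. Inflammatory genes were 7 higher and 4 lower of 11, with CXCL8 at 0.55, or 0.08 without cortisol array 3, and interferon-stimulated genes were 1 higher and 3 lower of 4, with MX2 at 0.25. TLR2 was well above background on 3 control and 4 cortisol arrays and changed sign with normexp background correction. Immediate early genes were 6 higher and 3 lower of 9, with MYC at 1.01 and FOS at 1.12, or 0.66 for FOS without cortisol array 6. Camera gave adjusted p of 0.183 for leukocyte, 0.394 for inflammatory (10 of the 11 genes, as 1 had an outlier spot), 0.865 for interferon-stimulated and 0.317 for immediate early genes.

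Genes that mark the other tissues in a muscle sample showed no list past the threshold. Extracellular matrix and fibroblast genes were 12 higher and 6 lower of 18, with VIM at 0.48 and MMP2 at 0.32. Adipocyte genes were 3 higher and 3 lower of 6, with PPARG at 0.38, and endothelial genes 2 higher and 5 lower of 7, with ROBO4 at -0.22 and NOS3 at -0.21. FABP4 had a higher mean after cortisol but was well above background on only 2 control and 4 cortisol arrays. Camera gave adjusted p of 0.392 for matrix, 0.786 for adipocyte and 0.786 for endothelial genes. Lists too short for the test were smooth muscle (MYLK 0.31, CNN1 -0.06), erythroid (HBB 1.29, or 0.74 without control array 4, and AHSP 0.50, 2 higher and 1 lower of 3), tendon and cartilage (TNMD -1.63, COL2A1 -1.03), Schwann cell (GFAP -0.29) and thyroid hormone action (THRB -0.52, beside MYH7, both lower). No cardiac marker was measured by name.

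Cell cycle genes were 4 higher and 2 lower of 6, with CCNB1 at 0.61 and PCNA at -0.14. Cytosolic ribosomal protein genes were 17 higher and 6 lower of 23, with RPS12 at 0.28. RPL32 had a lower mean after cortisol and was well above background on all 6 control and 2 cortisol arrays. Endoplasmic reticulum stress genes were 3 higher and 3 lower of 6, with HSPA5 at 0.27 and PDIA4 at -0.11, and heat shock genes 4 lower of 4, with CRYAB at -0.30 and HSPA1A at -0.23. Hypoxia and angiogenesis genes were 3 higher and 4 lower of 7, with ANGPT1 at -0.38 and VEGFA at -0.34, and antioxidant genes 2 higher and 3 lower of 5, with SOD1 at -0.36. UCP3 had 0.98, which was 0.00054 without control array 3. Camera gave adjusted p of 0.865 for cell cycle, 0.317 for ribosomal, 0.884 for endoplasmic reticulum stress, 0.786 for heat shock, 0.865 for hypoxia and 0.936 for antioxidant genes (4 of the 5, for the same spot as in the inflammatory list). The median and the test differ in sign for 3 lists, corticosteroid receptors, insulin and IGF signalling, and antioxidant genes.

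**Figure D2:**
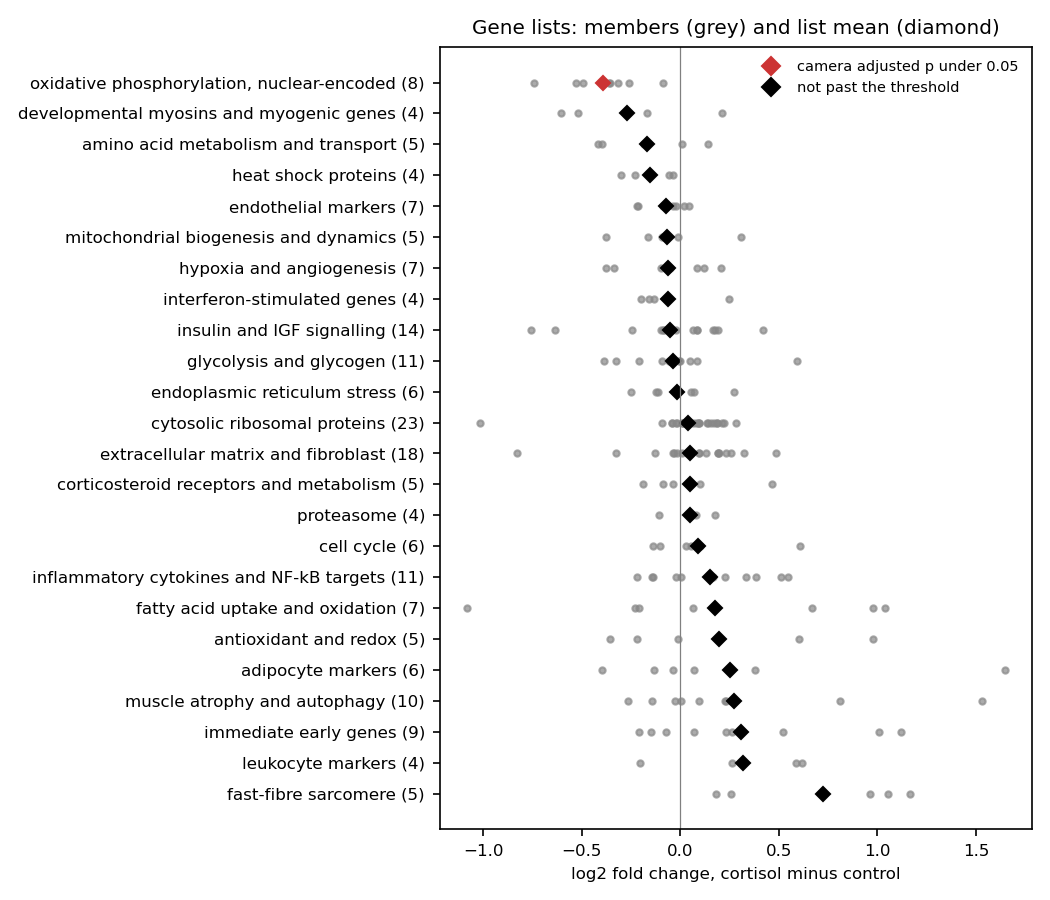
Log2 fold change, cortisol minus control, for the members (grey) and mean (diamond) of the 24 lists tested in camera, with the number of measured members in brackets. The nuclear-encoded oxidative phosphorylation list, at a mean of -0.39, is the 1 list past an adjusted p of 0.05 at the preset correlation.

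Of the 82 named genes, 63 kept the direction given here under every alternative tried. The other 19 had the other sign in at least 1 alternative and included HSD11B2, PSMB7, MYH2, NRF1, NOS3, CNN1, TLR2, MX2, HSPA5, CRYAB, VEGFA, UCP3, NR3C1, NR3C2, MSTN, IGF1, IGF2 and PPARGC1A. Leaving out 1 array moved the log2 fold change of 44 of the 82 by over 1.5 times or to the other sign. Besides those given above with such a value or sign change, they included TXNIP, PSMD4, IGFBP5, ME1, ROBO4, MYLK, AHSP, GFAP, TNMD, COL2A1, CCNB1, PCNA, PDIA4, HSPA1A, RPS12, ANGPT1 and THRB. None of the 20 genes nearest to the test was among the 44. They had been picked for a small unadjusted p over these same arrays, which favours genes that do not hinge on 1 array. Other alternatives moved several of the 20. Over all alternatives BAX lay between 0.07 and 0.49, FLAP between 0.18 and 0.93, ITGB2 between 0.20 and 0.78, MYC between 0.34 and 1.34 and COX5A between -0.94 and -0.35. FCER1G, HOXA4, SLAN, HAND1 and MYF5 were also moved by over 1.5 times in at least 1 alternative.

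Array quality was compared between the groups as a second question. The share of probes well above background averaged 71.4% ± 3.86 (SD, n = 6) in controls and 70.9% ± 2.16 after cortisol (exact permutation p of 0.758). The exact permutation p was 0.344 for the 75th percentile of signal, 0.792 for the local background and 0.506 for the slope of the spike-in probes. After adjustment over the 4 measures 0 differed, with 0 at an unadjusted p under 0.05. Between 1 and 6 spots per array carried an outlier flag, on average 2.67 in controls and 5.17 after cortisol, a measure that was not tested.

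**Figure D3:**
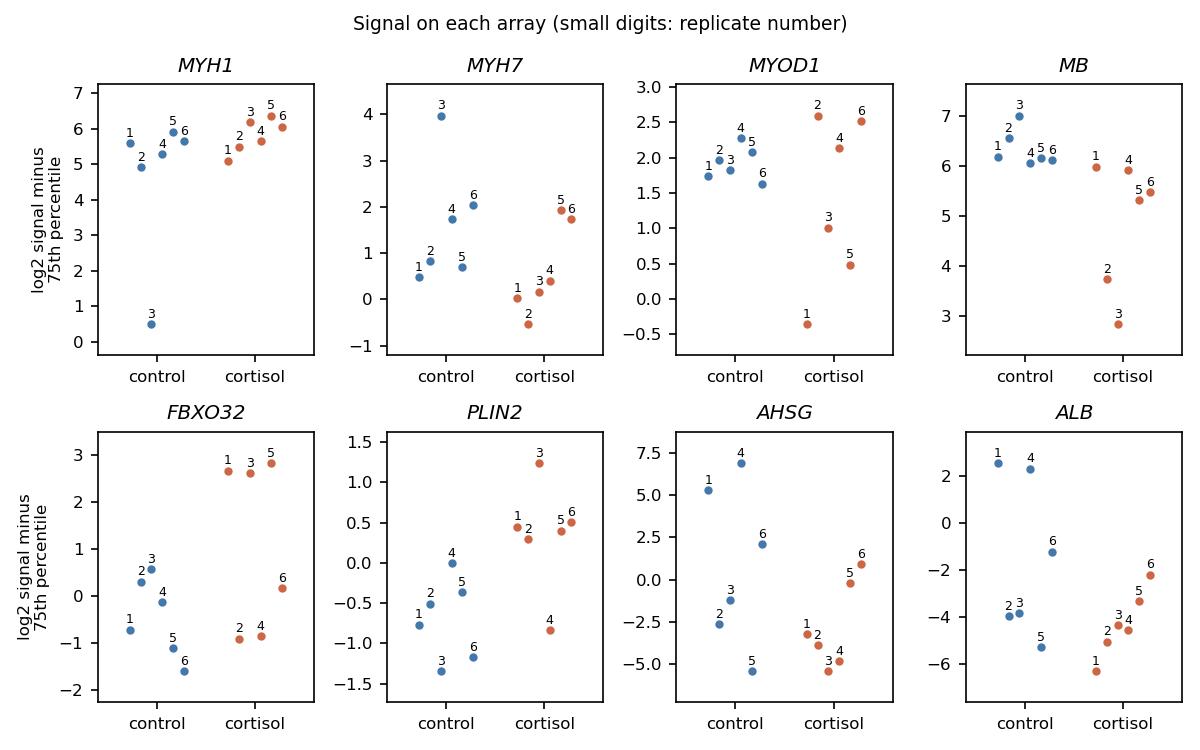
Log2 signal of 8 genes on each of the 12 arrays, with the replicate number beside each point (n = 6 arrays per group). MYH1 on control array 3 lies at 0.50 and AHSG on control arrays 1 and 4 at 5.31 and 6.92.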

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

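All tests of explanations in this part were chosen after the values had been seen. An array was singled out where its gap to the nearest other array of its group exceeded Dixon's limit for 6 samples, as a share of that group's range. Chance alone passes about 1 in 20 groups, and here 19 of 178 groups did. Over all tested probes the share was 7.81% in the control group and 5.96% in the cortisol group.

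Control array 3 stood apart for 7 of these 19 values. MYH1 was 0.50 there, MYH2 0.79, MSTN -3.37, UCP3 -6.86, COX15 -1.42 and PPARG -0.32, all below the other controls, while LPL was 4.58, above them. Defects of single spots are argued against, since all 7 separate fast-fibre probes, of 5 genes, were lower on this array than on every other control array. Heart muscle, which the treatment text of the labels names, is argued against by MYOD1 at 1.83, within the 1.63 to 2.27 of the other controls. A sample from a slower muscle, another part of the muscle or a fetus with other fibre types may explain it, as MYH7 was 3.97 there and at most 2.04 on the other controls, but MYH7 had been seen before it was chosen. A mislabelled sample was not tested, and the design names no biological difference within the control group.

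The other values past the limit are given without an explanation. On cortisol array 3, HSD11B1 was 1.99, CXCL8 -1.15 and RPS12 9.97, above the other cortisol arrays, and UCP3 was -2.78 and the slope of the spike-in probes 0.930, below them. On control array 1, HAND1 was -2.78, and on control array 2, ME1 was -1.33, both above the other controls. On control array 4, ITGB2 was -2.65, above the other controls, and the median local background was 18 intensity units against 21 to 22.5. On control array 5, TNMD was -6.78, below the other controls. On cortisol array 1, CRYAB was 8.66, above the other cortisol arrays. On cortisol array 6, 3 spots carried an outlier flag against 5 to 6 on the other cortisol arrays.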

How the results depend on the processing

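Chosen after seeing the data were the alternatives that leave out 1 doubted array per group, leave out the control arrays with liver transcripts, match lists without hand-made names, run camera against all tested probes, or test list means by exact permutation.

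The count of 0 probes past an adjusted p of 0.05 in limma stayed 0 in 30 of 33 alternatives. With slide 1 alone it was 1, a probe without a gene name whose log2 fold change was -7.31 there and -1.87 over all arrays. The looser thresholds gave 740 probes at an unadjusted p under 0.05 and 151 under 0.01. Leaving out each array in turn gave 0 to 0 probes, with 494 to 1089 at an unadjusted p under 0.05. The replicate block gave 0 probes, with 842 at an unadjusted p under 0.05. The numbers were not taken as pairs. Arrays of the same number had a mean correlation of 0.123, close to the 0.110 of other arrays that share a slide and row, although 4 of 6 such pairs exceeded 0.1 and 6 of 12 arrays correlated best with their own number.

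The count of lists depends on the set test. It fell from 1 to 0 with an estimated correlation, with fry and with the exact permutation test. The adjusted p of the oxidative phosphorylation list was 0.513, 0.0731 and 0.104 in these tests, which use the same fitted values and so the same mean of -0.39. The estimated correlation between its genes, 0.43 against the preset 0.01, is what ends the call in camera. With normexp 3 lists passed, as ribosomal (adjusted p of 0.00443) and fast-fibre genes (0.0338), both higher, joined it. Without the control arrays with liver transcripts, 1 and 4, 2 lists passed, as leukocyte genes joined it (0.0281). Leaving out each array in turn gave 1 to 2 lists, and the 2 arose without cortisol array 4, where ribosomal genes joined (0.0459). The cause of these added calls was not tested, and all were made at the preset correlation. In the main setting, camera with an estimated correlation gave adjusted p of 0.677 for leukocyte, 0.926 for fast-fibre and 0.926 for ribosomal genes. Over 32 alternatives the mean of the oxidative phosphorylation list lay between -0.46 and -0.30, and its adjusted p between 6.43e-07 and 0.513. With the replicate block its adjusted p was 0.000115.

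Array quality gave 0 of 4 measures with each array left out. Among the 82 named genes, 19 changed sign in at least 1 alternative. Since none of them had passed the test, these were not counted as reversed results. Signal over background limited the comparison to 10734 probes, as 4274 were too dim to test.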

Other observations

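All tests in this part, apart from the splits of the arrays, were chosen after the results had been seen, and the predictions for the splits were also set down after they had been run.

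Chance cannot be excluded for the count at an unadjusted p or for the count of lists. Of 100 splits of the 12 arrays drawn from 462, the real one included, 23 gave at least the 740 probes at an unadjusted p under 0.05 (highest other 1310). Splits that mix the slides unevenly raise that number, since 6 of the 49 splits with slides balanced as in the real one reached it (highest other 996), against 17 of the other 51. For probes past the adjusted threshold the splits decide nothing, since the real count is 0, which all 100 reach by construction (highest other 1). At least the 1 list past the threshold in camera arose in 71 of 100, and in 39 of the 49 balanced ones, with 5 lists in the highest other split, so camera at its preset correlation makes calls from regrouped arrays. For the oxidative phosphorylation list on its own, 2 of 100 splits gave a mean difference of at least 0.39 in size, and the highest other was 0.42. Both were among the 49 balanced splits, so the share there is 2 of 49. That list was picked because it had been called, so its 2 of 100 does not account for the choice among 24 lists.

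Lower oxidative phosphorylation genes after cortisol were set against other explanations. A bias shared by probes of like brightness is argued against, as 0.1% of 10000 random lists of the same signal had a mean as low. That share bears on brightness alone and is no measure of chance. The list had been picked because it was called, and genes drawn at random need not share its estimated correlation of 0.43. A smaller share of muscle fibres is argued against narrowly, and only by the fast-fibre and glycolysis genes. Without control array 3, these 16 genes had a mean difference of -0.05 and the oxidative phosphorylation genes of -0.43. The 2 are 0.37 apart (exact permutation p of 0.0476). The test was run in 4 forms, with or without that array and with or without 5 genes removed after their values were seen. They gave exact permutation p from 0.0108 to 0.0476, all against a list picked because it had been called. A smaller share is not excluded, since other muscle genes were lower over all arrays. MB was at -1.46, AQP4 at -1.20 and SLC2A4 at -0.76, although CAPN3 was at 0.01. A smaller share of slow fibres stays open, since MYH7 and the list had a Pearson r of -0.17 within groups (permutation p of 0.593, Spearman rho of -0.17 with p of 0.605, n = 12), and r was 0.43 without the 2 arrays farthest from the median. An effect of cortisol may remain, as a hypothesis.

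Liver transcripts were high on control arrays 1 and 4. AHSG was 5.31 and 6.92 there against -5.44 to 2.10 on the other arrays, and ALB 2.57 and 2.33 against -6.30 to -1.21. Liver tissue or RNA in those samples may be the source, from a list of 13 liver genes written after several of their values had been seen, of which 10 were measured. Of the 8 other than ALB and AHSG, 3 (TTR, TF and SERPINA1) were higher on both arrays than on every other, whereas 5 were not, among them SERPINC1, APOA1, C3 and PCK1, and PCK1 is also in the adipocyte list. APOA1 was -1.43 and -0.76 there against -2.67 to -0.86, and which of these genes fetal muscle itself expresses was not tested, so the source cannot be told apart from transcription in the muscle.

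Cortisol arrays differed among themselves. FBXO32 was 2.66, -0.91, 2.61, -0.86, 2.82 and 0.17 on cortisol arrays 1 to 6, and SLC25A33, chosen after its values were seen, was 2.88, -0.08, 2.49, -1.61, 2.59 and -0.52. The mean of the oxidative phosphorylation genes was 3.86, 4.20, 3.95, 4.28, 3.92 and 4.40 on the same arrays. Their scores on the first principal component, with 21.7% of the variance, were 25.5, -14.2, 51.7, -17.0, 40.01 and -10.5, and those of control arrays lay between -18.9 and -2.69. Control arrays lay between -1.60 and 0.56 for FBXO32. Positions within the slide row were 2, 4, 1, 3, 2 and 4 for cortisol arrays 1 to 6. For control arrays 1 to 6 they were 1, 3, 2, 4, 1 and 3. An effect of position was not tested. A wider spread between fetuses after cortisol may underlie this, but the mean distance between arrays was 0.783 in the cortisol group and 0.638 in the control group, with an exact permutation p of 0.0952.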
